A study of Homo sapiens with 18 samples.

How the data were processed

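RNA was measured by 3′ tag sequencing (QuantSeq 3′ mRNA-seq, Lexogen, read on a HiSeq4000) in HAP1 cells, a near-haploid human line derived from the KBM-7 chronic myeloid leukaemia line. Per the labels, 3 lines were used, 1 with an A allele and 2 with a C allele, and each was given DMSO or 10 uM Nutlin-3, an inhibitor of the p53 ubiquitin ligase MDM2, for 6 h. The labels do not name the variant, nor do they say how the lines were made or what a replicate number shares. The lines are called A, C1 and C2 here. Each of the 6 groups held 3 libraries, 18 in all, and no column of the table was left out.

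The deposited table held raw read counts per gene name. Per the file header and the labels, the authors aligned reads to GRCh37 with HISAT2 2.1.0 and counted those on the gene's own strand with featureCounts 1.6.2, merging all annotated genes of 1 name. Reads with several alignments and reads over more than 1 gene were not counted under that tool's default, so genes with near-identical copies can be undercounted or can take a copy's reads. No molecular identifiers were stated, so PCR copies count as reads. Because the assay reads the 3′ end, tags beyond the annotated end of a gene are missing from its count. The table had 55882 gene names, of which 31532 had no read and 131 lay on several chromosomes. The 37 mitochondrial genes held 0 reads in every library. Totals per library were 5277455 to 10098129 counts.

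Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13421 genes with 99.84% of the reads, among them 10 names on several chromosomes. TMM factors were 0.9227 to 1.042, and the common biological coefficient of variation was 0.145. A model with a mean for each of the 6 groups was fitted to all 18 libraries and tested with the quasi-likelihood F test. A gene was called where its Benjamini-Hochberg adjusted p was under 0.05. The 11 contrasts were Nutlin-3 against DMSO in each line and as the mean of the 3 lines, each C clone against A in each treatment, C2 against C1 in DMSO, and the difference of each C clone's response from that of A. Levels are CPM, the counts scaled to the library total and TMM factor, as mean ± SD over 3 libraries unless another n is given, changes are log2 fold changes with their SE, and adjusted p values are from edgeR unless another test is named.

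There were 19 gene lists: p53 activated targets, p53 pathway regulators, apoptosis regulators, G2/M and mitosis, S phase and DNA replication, cholesterol biosynthesis, interferon-stimulated genes, ATF4 and ER stress response, hypoxia and glycolysis, NRF2 antioxidant response, immediate early and MAPK feedback, NF-kB targets, cytosolic ribosomal proteins, oxidative phosphorylation, mesenchymal and matrix genes, epithelial genes, haematopoietic genes, neural genes and cancer-testis antigen genes. They were written from general knowledge and not chosen on these samples. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and p was adjusted over the 19 lists within each contrast. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move on balance one way and compares the list with no other genes.

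The contrasts, tests, lists, thresholds, the rule for named genes and all alternatives except 1 were fixed before the data were examined. MDM2 and CDKN1A were always named. For the mean response to Nutlin-3 the 12 largest changes each way were taken among called genes with an average log2 CPM of at least 2, and for single lines the 5 largest. For the C clones in DMSO the 12 highest and 12 lowest genes called with the same sign in both clones were taken by their smaller change, and the 5 largest each way among those called in a single clone. For the clones in Nutlin-3 the 5 largest each way of both-clone genes were taken, and for C2 against C1 the 5 each way with the smallest p. A list called by camera, or with at least 3 called members, gave its 4 members with the smallest p. Fewer are named where fewer passed. Other genes are named as chosen after their values were seen.

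Where a group had 1 to 3 counts in its libraries together, a ratio is given with its 95% counting interval, and where it had 0 counts, a bound against a floor of 3 counts over the group. Intervals and floors cover counting error only. The alternatives were DESeq2 1.42.0, RLE size factors in place of TMM, no filter on low counts, a fit to the compared libraries alone, the replicate number as a block, and the omission of each library in turn. The block was shared by all lines, so no fit paired libraries within a single line. After the data were seen, a fit without both replicate 2 libraries of the A line was added. Same-numbered libraries deviated together, with every correlation of their deviations over 0.1, for Nutlin-3 in A (0.26, 0.59 and 0.43) and for C1 against A in DMSO (0.11, 0.24 and 0.19). This pairing comes from the data, not from the labels, and the other contrasts did not meet that limit.

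The steps were tested on simulated data with 200 genes changed. For C1 against A in DMSO, 21.5%, 63.1% and 92.3% of genes changed 1.5-fold, 2-fold and 4-fold were called, with 3 false calls. For the mean response these shares were 71.2%, 94.0% and 100.0%, with 11 false calls. For the difference of response between C1 and A they were 1.54%, 30.8% and 80.0%, and between C2 and A 0.00%, 43.3% and 78.5%. A list raised 1.3-fold was called by camera (adjusted p = 4.65e-52) with 0 other lists, and with nothing changed 0 lists were called. Simulated genes varied independently of each other, so this did not test false calls of lists whose genes vary together. All simulated groups had the same spread per gene, and no libraries deviated together. The shares and false calls of single genes may therefore differ in the real libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.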

Results

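Gene expression was measured by 3′ tag sequencing in 18 libraries of HAP1 cells. The cells came from 3 lines, A with the A allele and the clones C1 and C2 with the C allele of a variant that the labels do not name. Each line received DMSO or Nutlin-3, which blocks MDM2, the ligase that marks p53 for degradation, at 10 uM for 6 h, with 3 libraries per group. The series concerns variants of the p53 pathway and the response to drugs. Library totals ran from 5277455 to 10098129 counts, with a median of 7566967.

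The line set the main differences between libraries. The first 2 principal components of log2 CPM, with 25.2% and 19.6% of the variance, separated A, C1 and C2, and the third (11.3%) set both replicate 2 libraries of A apart from all others. Replicates of the A groups that included replicate 2 differed with a chi-square per degree of freedom of 17.5 to 36.9, against 4.31 to 9.55 for all other replicate pairs. The same libraries had the lowest TMM factors, 0.9479 in DMSO and 0.9227 in Nutlin-3. Counts without both of them are given beside the results, as a choice made after the data were seen.

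**Figure D1:**
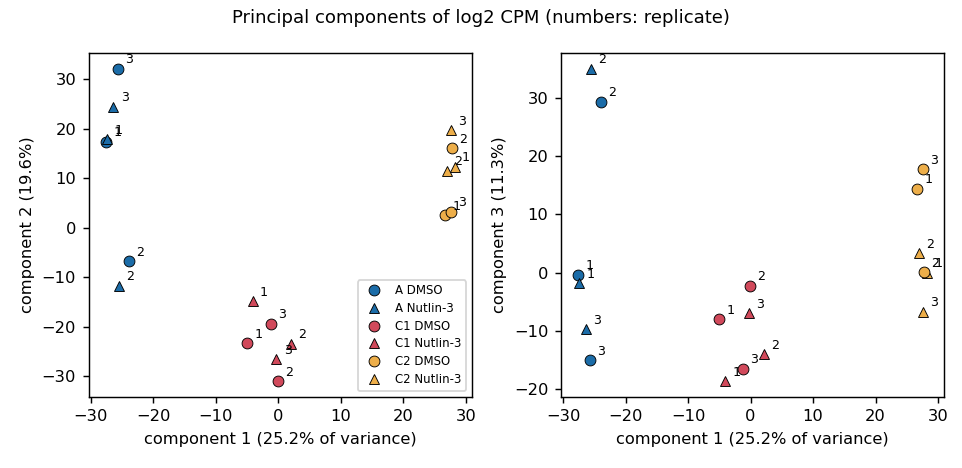
Principal components of log2 CPM for all 18 libraries, with component 1 (25.2% of variance) against component 2 (19.6%) on the left and against component 3 (11.3%) on the right. Colours mark lines, circles DMSO, triangles Nutlin-3 and numbers the replicate, and both A replicate 2 libraries lie apart on component 3.

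MDM2, a target and the main negative regulator of p53, and CDKN1A, which encodes the cell cycle inhibitor p21, did not pass the test in any comparison. In DMSO the log2 fold change of MDM2 was -0.10 in C1 against A (adjusted p = 0.844) and 0.15 in C2 (adjusted p = 0.806). CDKN1A was at 5.85 ± 2.95 CPM in A, 6.54 ± 1.86 in C1 and 6.43 ± 1.21 in C2, with log2 values of 0.14 (adjusted p = 0.905) and 0.12 (adjusted p = 0.942). The sign of the C1 value turned without C1 DMSO replicate 1 (-0.07) and without A DMSO replicate 3 (-0.17), and that of C2 without C2 DMSO replicate 2 (-0.01) and without A DMSO replicate 3 (-0.19).

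Nutlin-3 was compared with DMSO to find the response to MDM2 inhibition, first as the mean of the 3 lines (9 libraries against 9). SLC7A11, the cystine/glutamate antiporter, rose from 47.0 ± 7.35 to 105 ± 24.5 CPM (log2 1.13, SE 0.09, adjusted p = 1.87e-06), and DDIT4, an inhibitor of mTORC1, from 24.4 ± 7.96 to 53.5 ± 12.2 (log2 1.16, SE 0.15, adjusted p = 0.000524). HSPA5, the chaperone BiP of the endoplasmic reticulum (ER), rose from 2070 ± 176 to 3150 ± 407 CPM (log2 0.60, SE 0.07, adjusted p = 0.000119). ADM2, which encodes a peptide hormone, rose from 5.10 ± 1.32 to 11.7 ± 3.68 CPM (log2 1.16, SE 0.16, adjusted p = 0.00159). CYR61, a matricellular protein, fell from 230 ± 81.8 to 160 ± 54.1 CPM (log2 -0.53, SE 0.09, adjusted p = 0.00911).

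In all, 50 genes were called in the mean response, 40 higher and 10 lower, and 4 of them changed at least 2-fold. All 50 had the same sign in the 3 lines, which their choice by the mean of these same lines favours. Other transporters that rose were SLC6A9 for glycine (log2 0.92, adjusted p = 0.0031) and SLC1A4 for neutral amino acids (log2 0.68, adjusted p = 0.000287). ULBP1, a ligand of the NKG2D receptor, rose by log2 0.82 (adjusted p = 0.00582), and the secreted glycoprotein STC2 rose from 113 ± 31.3 to 179 ± 20 CPM. HERPUD1, which acts in ER-associated degradation, rose by log2 0.64 (adjusted p = 0.0144), the transcription factors ATF3 and JDP2 by 0.67 and 0.66, and RP11-265D19.6 by 0.65. Lower were KRCC1 (5.32 to 2.66 CPM, log2 -1.0, adjusted p = 0.0159), a transcript on chromosome 12 that has only a clone name (GRCh37 3150603 to 3154116, log2 -0.62), RHOBTB1 (log2 -0.50), the engulfment adaptor GULP1 (log2 -0.45) and KIAA1430 (log2 -0.43, adjusted p = 0.0113). The RNA polymerase I subunit CD3EAP (log2 -0.33), CHCHD4 of mitochondrial import (log2 -0.30), SMIM10 (log2 -0.29) and the ribosome biogenesis factor PNO1 (log2 -0.25) were also lower. Of the 18 omissions of 1 library, 9 ended the call of ATF3, 7 of JDP2, 12 of RP11-265D19.6, 11 of the chromosome 12 transcript, 13 of GULP1, 13 of CHCHD4, 14 of SMIM10, 15 of RHOBTB1 and 15 of PNO1, with an adjusted p of at most 0.118. Without both A replicate 2 libraries the calls of RHOBTB1 (adjusted p = 0.0562) and SMIM10 (0.0625) ended, and with no filter on low counts those of SMIM10 (0.0942) and PNO1 (0.266). HERPUD1, KRCC1 and CD3EAP lost theirs without C1 DMSO replicate 2 (adjusted p = 0.0512, 0.0558 and 0.0520) and without C1 Nutlin-3 replicate 2 (adjusted p = 0.0503 each).

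The count of 50 rose to 95 without A Nutlin-3 replicate 2 and fell to 23 without C1 DMSO replicate 2, 25 without C1 Nutlin-3 replicate 2, and 31 without each of C2 DMSO replicate 2, C2 Nutlin-3 replicate 2 and C1 DMSO replicate 3. It was 98 without both A replicate 2 libraries, and 47 of the 50 were among these. DESeq2 called 147, with all 50 among them, and 159 were called with no filter on low counts, 48 of the 50 among them.

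The ATF4 and ER stress list held the clearest group response to Nutlin-3. All 34 tested members had a positive mean log2 fold change, with a median of 0.35 and a mean of 0.42, and 11 rose by the test over all genes (28 adjusted over the list alone). Camera gave the list an adjusted p of 4.92e-39, 1.08e-05 with an estimated correlation. Its 4 members with the smallest p were SLC7A11, HSPA5, DDIT4 and XBP1, the transcription factor of the unfolded protein response, which rose from 121 to 176 CPM (log2 0.55, adjusted p = 0.0031). ATF4 itself rose by log2 0.42 (adjusted p = 0.031) and DDIT3 by 0.59 (adjusted p = 0.031), both chosen after their values were seen. The NRF2 antioxidant list also rose (23 tested, median 0.12, camera adjusted p = 0.000226, and adjusted p = 0.0153 with an estimated correlation), although SLC7A11 alone passed over all genes and 2 members adjusted over the list alone. SLC7A11 is also on the ATF4 and ER stress list, and the NRF2 list was not tested without it.

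Targets that p53 activates did not rise as a group. Of 69 tested, 28 had a positive mean log2 fold change. The median was -0.03, the mean 0.04 and the direction of the test upward (camera adjusted p = 0.874). Over all genes 3 members rose, namely DDIT4, SESN2, a stress-induced sestrin (76.1 to 110 CPM, log2 0.53, adjusted p = 0.0141), and BBC3, the pro-apoptotic PUMA (53.7 to 70.8 CPM, log2 0.40, adjusted p = 0.0264), and adjusted over the list alone 5 were higher and 1 lower. DDIT4 and SESN2 are also on the ATF4 and ER stress list. BBC3 lost its call in 8 of the 18 omissions of 1 library (adjusted p at most 0.0742). MDM2 was at 102 ± 15.1 CPM with Nutlin-3 and 92.0 ± 11.9 with DMSO (log2 0.15, SE 0.09, adjusted p = 0.685). CDKN1A was at 7.44 ± 1.71 and 6.27 ± 1.87 CPM (log2 0.26, SE 0.18, adjusted p = 0.775).

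**Figure D2:**
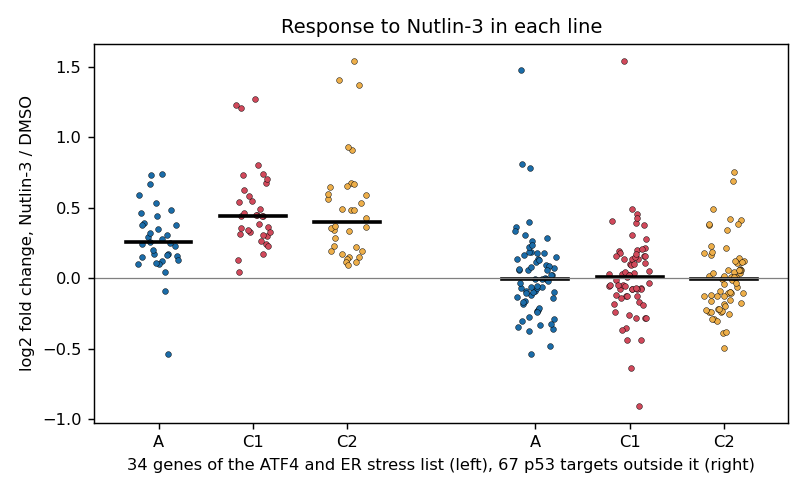
Log2 fold change of Nutlin-3 over DMSO for each of the 34 genes of the ATF4 and ER stress list (left) and 67 p53 targets outside that list (right) in lines A, C1 and C2, where a point is a gene and a bar the median of the group. The medians of the ATF4 and ER stress list are 0.25 in A, 0.44 in C1 and 0.40 in C2.

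None of the other lists was called for the mean response. The camera adjusted p was 0.315 for p53 pathway regulators (0 called), 0.898 for apoptosis regulators, 0.113 for G2/M and mitosis, 0.315 for S phase and DNA replication, 0.113 for cholesterol biosynthesis, 0.827 for interferon-stimulated genes and 0.315 for hypoxia and glycolysis. It was 0.428 for immediate early and MAPK feedback genes, 0.957 for NF-kB targets, 0.956 for cytosolic ribosomal proteins, 0.874 for oxidative phosphorylation, 0.576 each for mesenchymal and for epithelial genes, 0.113 for haematopoietic genes, 0.203 for neural genes and 0.315 for the cancer-testis list, of which only PRAME was tested. Single members moved in some of these: the pro-apoptotic HRK rose with BBC3 among apoptosis regulators (log2 0.49, adjusted p = 0.0206), the collagen prolyl hydroxylase subunit P4HA2 rose in the hypoxia list (log2 0.43, adjusted p = 0.00349), and ATF3 rose and CYR61 fell among immediate early genes. HRK and P4HA2 were chosen after their values were seen. Adjusted over the list alone, 3 apoptosis regulators and 2 hypoxia genes were higher, and 3 immediate early genes were higher and 2 lower. The median, mean and test differed in sign for p53 targets, apoptosis regulators (median -0.05, mean -0.0046, test up), interferon-stimulated genes (median 0.03, mean -0.0015, test up), NF-kB targets (median 0.06, mean 0.0061, test down) and ribosomal proteins (median -0.0012, mean 0.0039, test down).

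Within single lines few genes passed. In C1, SLC7A11 rose from 49.6 ± 4.05 to 116 ± 14.3 CPM (log2 1.23, SE 0.16, adjusted p = 0.00308), ADM2 from 4.97 ± 1.09 to 15.7 ± 1.75 (log2 1.66, SE 0.27, adjusted p = 0.0308), and TSC22D3, the glucocorticoid-induced leucine zipper, from 100 ± 8.32 to 169 ± 7.46 (log2 0.76, SE 0.11, adjusted p = 0.0156). In C2, SLC7A11 alone passed, rising from 46.5 ± 4.34 to 124 ± 8.78 CPM (log2 1.41, SE 0.16, adjusted p = 0.000452), while DDIT4 was at log2 1.54 (adjusted p = 0.0615). In A no gene passed, in a test that did not use the pairing of its libraries. SLC7A11 there was at 44.8 ± 12.8 and 75.0 ± 7.96 CPM (log2 0.74, SE 0.16, adjusted p = 0.361), and the smallest adjusted p was 0.0533, for HSPA5 (log2 0.73, SE 0.12).

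The counts of called genes were thus 0 in A, 3 in C1 and 1 in C2, with 540, 481 and 925 at an unadjusted p under 0.05, and DESeq2 called 7, 7 and 22. In A, 2 genes were called without A Nutlin-3 replicate 1, 2 without A DMSO replicate 2 and 2 without both A replicate 2 libraries. In C1 the count fell to 0 without C1 DMSO replicate 2 and to 1 without C1 DMSO replicate 1 and without each of the C1 Nutlin-3 replicates 1, 2 and 3, and it was 9 without both A replicate 2 libraries. The call of ADM2 in C1 was lost with every one of the 6 omissions (adjusted p = 0.0713 to 0.562) and with the replicate block (0.0644), and that of SLC7A11 without C1 DMSO replicate 2 (adjusted p = 0.0678). TSC22D3 lost its call without C1 DMSO replicate 1 (adjusted p = 0.118) or 2 (0.320) and without C1 Nutlin-3 replicate 1 (0.0713), 2 (0.181) or 3 (0.0736). In C2 the count was 2 without C2 DMSO replicate 3 and 22 without both A replicate 2 libraries.

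The ATF4 and ER stress list rose in each line, with 32 of 34 members positive in A, 34 in C1 and 34 in C2. The camera adjusted p was 2.71e-14, 3.44e-34 and 2.96e-22, and 0.00177, 2.22e-05 and 0.000209 with an estimated correlation. Members higher were 0, 1 and 1 over all genes and 6, 23 and 21 adjusted over the list alone. The NRF2 list was called in A (adjusted p = 0.00467, and adjusted p = 0.056 with an estimated correlation) and C1 (adjusted p = 0.0063, and adjusted p = 0.0647 with an estimated correlation) and not in C2 (adjusted p = 0.108). Its call in A was lost without A Nutlin-3 replicate 1 (adjusted p = 0.0702), A DMSO replicate 2 (0.0738), A Nutlin-3 replicate 2 (0.0517) or both A replicate 2 libraries (0.0538), and in C1 without C1 Nutlin-3 replicate 1 (0.0567). The p53 targets had medians of -0.0049 in A, 0.02 in C1 and 0.0056 in C2 (camera adjusted p = 0.794, 0.625 and 0.902).

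Whether the C clones responded to Nutlin-3 differently from A was tested as the difference between the responses. As a group, the ATF4 and ER stress genes had a larger response in C1 than in A by camera, with a median difference of log2 0.15 and 28 of 34 members positive (adjusted p = 0.00207, but adjusted p = 0.317 with an estimated correlation). In C2 the median difference was 0.20 with 25 of 34 positive (adjusted p = 0.0251, but adjusted p = 0.618 with an estimated correlation). The difference for SLC7A11 was 0.49 in C1 and 0.67 in C2, and for the amino acid transporter SLC7A5 0.83 and 1.19, none of them past the test (adjusted p = 1.00 in C1 and 0.990 in C2). The C1 call was lost without A DMSO replicate 1 (adjusted p = 0.116) and without A Nutlin-3 replicate 3 (0.0501). The C2 call was lost without A DMSO replicate 1 (0.381), A Nutlin-3 replicate 1 (0.0944), A Nutlin-3 replicate 3 (0.271), C2 DMSO replicate 2 (0.291) or C2 Nutlin-3 replicate 2 (0.240). Fry called neither (adjusted p = 0.475 in C1 and 0.462 in C2). Of single genes, edgeR called 0 for C1 and 0 for C2, with 285 and 357 at an unadjusted p under 0.05, and DESeq2 called 0 and 0. With no filter on low counts there were 31 and 26, and without both A replicate 2 libraries 1 and 0. Of the 40 genes that rose in the mean response, 29 rose more in C1 and 29 more in C2 than in A by their fitted values, which was not tested as a count.

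The clones were compared with A in DMSO to find what went with the C allele before treatment. ZNF793, a zinc finger gene, fell from 51.6 ± 0.49 CPM in A to 1.03 ± 0.371 in C1 and 0.410 ± 0.216 in C2, 50.9-fold and 118-fold lower. FASTKD2, a mitochondrial RNA-binding protein, fell from 51.5 ± 5.13 to 4.30 ± 3.13 and 0.305 ± 0.239, and BMP7, a bone morphogenetic protein, from 25.3 ± 3.55 to 2.07 ± 1.54 and 1.09 ± 0.311. ACTL8 fell from 371 ± 85.8 to 39.5 ± 5.31 and 13 ± 1.21 CPM, and DHRS2, a short-chain dehydrogenase, from 113 ± 19.8 to 9.30 ± 1.57 and 14.7 ± 2.91. In the other direction, TMEM35, a chaperone of nicotinic receptors, rose from 5.59 ± 0.835 to 44.8 ± 5.80 and 32.2 ± 1.44 CPM, and THY1, a surface glycoprotein, from 1.29 ± 0.125 to 23.1 ± 1.52 and 4.45 ± 1.36.

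In DMSO 364 genes were called in C1 (160 higher, 204 lower) and 447 in C2 (191 higher, 256 lower), with 249 and 302 at least 2-fold. Of these, 188 had the same sign in both clones, 64 higher and 124 lower, and 19 had opposite signs. Independent lists of these sizes would share 2.28 higher and 3.89 lower genes. Because both comparisons use the same A libraries, unchanged groups were also simulated against shared A libraries, and 0 genes were shared in the mean of 50 simulations. The covariance of the fold changes across genes was 0.18, against 0.0372 simulated for shared libraries alone. Their correlation was 0.547 against 0.496 simulated, and 70.9% of genes had the same sign against 66.6%. By these 2 measures over all genes the agreement was close to that from shared libraries alone. The simulation gave all groups the same spread per gene, so it can understate the noise of the A libraries. With no library in common, C1 in DMSO and C2 in Nutlin-3 shared 190 genes, and C2 in DMSO and C1 in Nutlin-3 shared 173. Because A libraries of the same number deviated together across treatments (correlation 0.26, 0.59 and 0.43 for numbers 1, 2 and 3), both comparisons were repeated with A libraries of different numbers, 1 in one and 2 in the other, the lone one taken to vary like the other groups. Over all such choices 111 to 174 genes were shared, while independent lists would share 2.96 to 21, or 114 in the choice with 174.

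Other genes higher in both clones were PAX2, a paired-box transcription factor (log2 2.19 in C1 and 1.73 in C2), the retinol receptor STRA6 (2.66 and 2.30), ANGPTL2 (3.32 and 1.84), SERPINF1, the secreted factor PEDF (1.49 and 1.49), the prostaglandin E2 receptor PTGER3 (1.75 and 1.46), FAM19A5 (1.44 and 2.50) and the flippase ATP8A2 (1.41 and 1.69). The non-coding CTD-2311M21.2 (3.61 and 3.05) and LINC00152 (1.58 and 2.06) and the mitochondrial pseudogene MTND6P4 (1.44 and 1.45), which may hold mitochondrial reads since the mitochondrial genes themselves have none, were also higher. Other genes lower in both were LINC00665 (-4.62 and -5.74), WBP5 (-4.22 and -5.01), ZNF814 (-3.23 and -3.91), the enamel matrix gene AMBN (-2.87 and -5.85) and ZCCHC12 (-2.83 and -3.25). MEIOB fell by 3.94 in C1 and had 1 count in C2 against 235 in A (ratio interval 36.4 to 8130). FOLH1, a membrane peptidase with a near-identical copy, fell by 3.51 in C2 and had 3 counts in C1 against 237 in A (ratio interval 28.5 to 412). All of these had an adjusted p of at most 0.00273 in both clones, and none lost its call with any 1 library left out. Of the 124 lower genes, 34 were at least 8-fold lower in both clones.

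**Figure D3:**
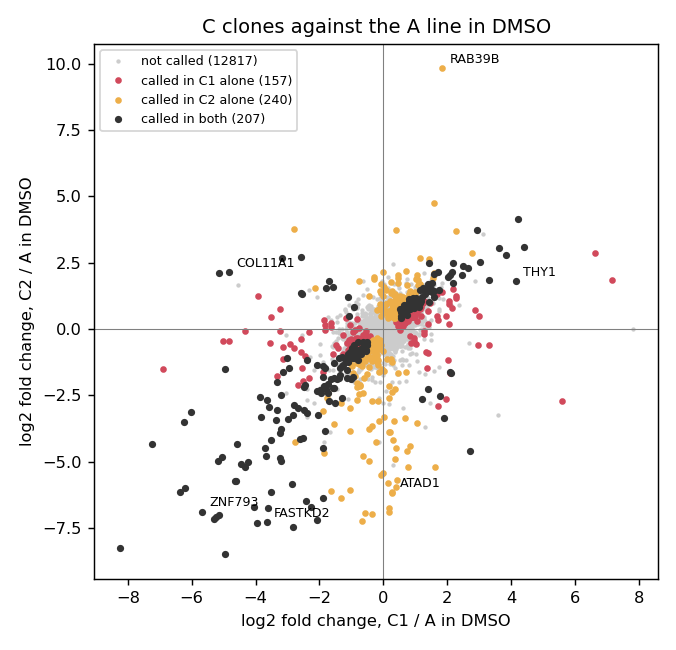
Log2 fold change against A in DMSO for 13421 genes, C1 on the horizontal and C2 on the vertical axis, where a point is a gene and colours mark genes called in neither, in 1 or in both clones. Of the genes called in both, 188 lie with the same sign and 19 with opposite signs, and ATAD1 lies far below 0 in C2 alone.

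The call counts for single clones depended on the A replicate 2 libraries. Without both of them 1455 genes were called in C1, 909 in C2 and 541 in both with the same sign, and these held 356 of the 364, 429 of the 447 and 183 of the 188. Without C1 DMSO replicate 2 the C1 count was 225. A fit to the compared libraries alone called 211 in C1 and 249 in C2, no filter on low counts gave 630, 676 and 293, and DESeq2 gave 409, 507 and 204.

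In C1 alone, 157 genes were called. EPHX2, the soluble epoxide hydrolase, rose from 1.62 ± 0.728 to 12.7 ± 2.78 CPM (log2 2.96, adjusted p = 3.5e-06), and the AMPA receptor subunit GRIA2 (log2 1.70), ARHGAP44 (log2 1.69) and QPRT of NAD synthesis (log2 1.38) also rose. IRX4, a homeobox gene, fell from 9.01 ± 0.972 to 0.410 ± 0.284 CPM (log2 -4.34, adjusted p = 1.44e-07), and EMC10, of the ER membrane complex, from 25.6 ± 4.70 to 2.41 ± 1.92 (log2 -3.50, adjusted p = 5.69e-07). ZNF256 (log2 -3.54), the kinase SYK (log2 -2.32) and the annexin ANXA1 (log2 -1.86) were lower too. AC091633.2 was called at log2 2.05 (adjusted p = 0.0469), but its level in C1 was 33.2 ± 33.6 CPM, and without C1 DMSO replicate 2 the value was 0.78 (adjusted p = 0.664). The call of AC091633.2 also ended without A DMSO replicate 1 (adjusted p = 0.137), 2 (0.0738) or 3 (0.176), with the replicate block (log2 1.84, adjusted p = 0.0642), with DESeq2 (0.0568) and with the compared libraries alone (0.154). Over all alternatives its adjusted p ranged from 8.96e-22, with no filter on low counts, to 0.664.

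In C2 alone, 240 genes were called. RAB39B, a Rab GTPase gene, had 15 ± 0.308 CPM in C2 and 0 counts in A, at least 109-fold higher (adjusted p = 3.36e-09). CHMP4C, of the ESCRT-III complex, rose from 0.699 ± 0.180 to 9.57 ± 0.704 CPM (log2 3.75), DLK1 from 6.55 ± 1.63 to 29 ± 2.88 (log2 2.15) and AC091493.2 by log2 1.89. ATAD1, an ATPase of the outer mitochondrial membrane, fell from 83.4 ± 16.3 to 1.15 ± 0.330 CPM (log2 -6.14, SE 0.23, adjusted p = 6.82e-13). TNFAIP2 fell from 40.9 ± 9.13 to 0.33 ± 0.2 (log2 -6.93, adjusted p = 5.22e-11), the granzyme B inhibitor SERPINB9 from 27.3 ± 4.72 to 0.218 ± 0.193 (log2 -6.90, adjusted p = 3.71e-11) and the esterase IAH1 by log2 6.19. RP3-522D1.1 had 1 count in C2 against 190 in A (ratio interval 29.4 to 6580). MTRNR2L8, a nuclear copy of mitochondrial sequence, was called at log2 2.20 (39.6 ± 31.7 against 8.66 CPM), and its call ended without A DMSO replicate 1 (adjusted p = 0.0573), without C2 DMSO replicate 1 (adjusted p = 0.111) and with the compared libraries alone (adjusted p = 0.0527).

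Targets of p53 did not differ as a group between the clones and A in DMSO. For the 69 tested members the median was -0.02 in C1 (mean -0.02, test up, camera adjusted p = 0.870) and 0.0029 in C2 (mean -0.04, test up, camera adjusted p = 0.917). Single members were lower, HES2 (log2 -1.59, adjusted p = 0.000159) and KITLG (log2 -0.96, adjusted p = 0.00187) in C1, and HES2 (log2 -2.21, adjusted p = 7.77e-06) and SFN (log2 -2.1, adjusted p = 0.0375) in C2, which were chosen after their values were seen. Adjusted over the list alone the counts were the same, 0 higher and 2 lower in each clone. The camera adjusted p of the p53 pathway regulators was 0.535 in C1 and 0.987 in C2.

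Of 23 tested members of the NRF2 antioxidant list, 3 rose in C1 over all genes and 5 adjusted over the list alone. The aldo-keto reductase AKR1C3 rose from 1.27 ± 0.293 to 5.40 ± 0.865 CPM (log2 2.05, adjusted p = 0.000126), the ferritin light chain FTL, which has near-identical copies, from 338 ± 27.1 to 529 ± 15.5 (log2 0.64, adjusted p = 0.000636), and the autophagy receptor SQSTM1 from 159 to 208 (log2 0.38, adjusted p = 0.0386), while GCLC was at log2 0.39 (adjusted p = 0.0695). Camera called the list (adjusted p = 0.0141, but adjusted p = 0.0967 with an estimated correlation). The list's call was lost without A DMSO replicate 2 (adjusted p = 0.128) and without both A replicate 2 libraries (0.126), and that of SQSTM1 in each of the 6 omissions (adjusted p = 0.0541 to 0.175), with no filter on low counts (0.135) and with the compared libraries alone (0.224). PRAME, the only tested gene of the cancer-testis list, fell from 51.8 ± 16 to 14.1 ± 1.06 CPM in C1 (log2 -1.88, adjusted p = 2.53e-05) and to 19.7 ± 3.33 in C2 (log2 -1.39, adjusted p = 0.000603). Camera adjusted p for that list was 0.007 and 0.0212, and 0.0742 and 0.0792 with an estimated correlation. No further list was called in C1, where every other camera adjusted p was at least 0.294.

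In C2, camera called the epithelial and ribosomal protein lists lower. Of 11 tested epithelial genes 2 fell over all genes and 4 adjusted over the list alone: the membrane protein MAL2 from 15.1 ± 10.6 to 1.47 ± 0.993 CPM (log2 -3.32, adjusted p = 0.00488), and the tight junction gene CLDN7 from 39 counts in A to 1 (ratio interval 5.76 to 1380), while ESRP1 was at log2 -1.34 (adjusted p = 0.0569) and EPCAM at -1.77 (adjusted p = 0.120). Camera adjusted p for the list was 0.00401, and 0.0358 with an estimated correlation. In C1 the epithelial list was not called (camera adjusted p = 0.307). There EPCAM alone fell over all genes, and 2 members fell adjusted over the list alone. In C2, of 76 ribosomal protein genes only 6 had a positive fold change, with a median of -0.15 (camera adjusted p = 7.12e-05, and adjusted p = 0.0358 with an estimated correlation), but 0 passed singly, over all genes or adjusted over the list alone. RPL36 was at log2 -0.35 (adjusted p = 0.055), RPS16 at -0.30, RPL10 at -0.72 and RPL37 at 0.45. Oxidative phosphorylation genes had a median of -0.13 with 0 of 62 called (NDUFA1 at log2 -0.48, SDHA at -0.27, ATP5D at -0.42 and NDUFB4 at -0.26). Camera called that list (adjusted p = 0.0248, but adjusted p = 0.241 with an estimated correlation), and the call was lost without A DMSO replicate 1 (adjusted p = 0.0512), A DMSO replicate 3 (0.101) or C2 DMSO replicate 3 (0.0922). Mesenchymal genes went both ways in C2 (camera adjusted p = 0.907): THY1 and FN1, which encodes fibronectin (54.0 ± 11.7 to 97.0 ± 22.7 CPM, log2 0.85, adjusted p = 0.0212), rose, and S100A4 (log2 -1.17), the transcription factor SNAI1 (log2 -1.28) and TIMP3 (log2 -0.94) fell. Adjusted over the list alone 2 mesenchymal genes were higher and 4 lower. Leaving out 1 library ended the call of FN1 in 3 of 6 cases (adjusted p at most 0.160), of SNAI1 in 4 (at most 0.149) and of S100A4 in 2 (at most 0.0932). The compared libraries alone ended all 3 calls (adjusted p = 0.055, 0.0719 and 0.0818 for FN1, SNAI1 and S100A4).

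In Nutlin-3 the clones differed from A in much the same way. ZNF793 was at 52.5 ± 8 CPM in A, 1.09 ± 0.410 in C1 and 0.609 ± 0.108 in C2 (log2 -5.58 and -6.40). LINC00665 (log2 -5.54 and -5.29), WBP5 (log2 -4.82 and -4.77), MEIOB (log2 -4.17 and -5.64) and FASTKD2 (log2 -4.03 and -7.36) were lower, and TMEM35 (log2 3.09 and 2.31), ANGPTL2 (log2 3.86 and 2.75), PAX2 (log2 2.52 and 2.07), CTD-2311M21.2 (log2 3.28 and 2.62) and LINC00152 (log2 2.03 and 2.1) higher. In C1 360 genes were called (165 higher, 195 lower) and in C2 556 (257 higher, 299 lower), 211 of them with the same sign in both, 85 higher and 126 lower. Of the genes called in DMSO, 258 in C1 and 339 in C2 were called with the same sign in Nutlin-3, and 48 higher and 96 lower genes were shared by both clones in both treatments. Without both A replicate 2 libraries the counts were 728 in C1 and 573 in C2, with 335 and 443 of the genes shared. With no filter on low counts C1 had 567, the compared libraries alone gave 215 and 315, and DESeq2 gave 434 and 640.

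Among lists, the NRF2 list was higher in C1 in Nutlin-3 (camera adjusted p = 0.00344, and adjusted p = 0.0485 with an estimated correlation), with AKR1C3 (log2 1.62), FTL (log2 0.59), AKR1C1 (log2 1.38) and SLC7A11 (log2 0.63) called, 4 over all genes and 4 adjusted over the list alone. PRAME was lower (log2 -2.02), and its list had a camera adjusted p of 0.00185, 0.0403 with an estimated correlation. In C2 camera called no list, the smallest adjusted p being 0.0505, for ribosomal proteins and for the cancer-testis list. Of the p53 targets in C2 (camera adjusted p = 0.881) the transcription factor gene HES2 fell from 11 ± 1.24 to 1.63 ± 0.370 CPM (log2 -2.74, adjusted p = 2.33e-07) and SFN, which encodes 14-3-3 sigma, from 4.04 to 0.557 (log2 -2.82, adjusted p = 0.00237), while the decoy receptor gene TNFRSF10D rose from 5.62 to 9.65 (log2 0.78, adjusted p = 0.00113). SLC7A11 (log2 0.72) of the NRF2 list also rose in C2, and SQSTM1 (log2 0.41) and AKR1C3 (log2 0.99, adjusted p = 0.0497) were called with less support, while MAL2 (log2 -2.81), ESRP1 (log2 -1.47) and CLDN7 (1 count against 46, ratio interval 7.45 to 1760) of the epithelial list fell. THY1 rose in both clones and SPARC (log2 1.05) in C1, and SNAI1 fell in both (log2 -1.10 and -1.27), with TIMP3 (log2 -1.08) and S100A4 (log2 -0.87) in C2. Adjusted over the list alone, in C2 1 p53 target was higher and 2 lower, 4 NRF2 genes higher and 1 lower, 1 epithelial gene higher and 4 lower, and 4 mesenchymal genes higher and 3 lower. Leaving out 1 of 6 libraries ended the call of AKR1C1 in 4 cases, SLC7A11 in 3 and SNAI1 in 4 in C1, and of AKR1C3 in 5, SQSTM1 in 3, S100A4 in 5, SNAI1 in 3, TIMP3 in 2, ESRP1 in 5 and MAL2 in 1 in C2, with an adjusted p of at most 0.214. In C2 the AKR1C3 call also ended with DESeq2 (adjusted p = 0.0775), RLE factors (0.0529), no filter on low counts (0.0865) and without both A replicate 2 libraries (0.148), and over all alternatives its adjusted p ranged from 0.0167 to 0.232. SQSTM1 lost its call in C2 with no filter (0.0609, range 0.000815 to 0.184), AKR1C1 in C1 without both A replicate 2 libraries (0.0701) and S100A4 in C2 with the replicate block (0.0534). The compared libraries alone ended the calls of FTL, AKR1C1, SLC7A11 and SNAI1 in C1 and of TNFRSF10D, SQSTM1, AKR1C3, SNAI1 and S100A4 in C2 (adjusted p = 0.0502 to 0.232).

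The clones of the same allele were compared with each other in DMSO. COL11A1, a fibrillar collagen, was at 40.7 ± 0.597 CPM in C2 and 0.317 ± 0.183 in C1 (log2 7, adjusted p = 1.07e-12), and TMEM47 at 71.4 and 4.91, FBXO17 at 47.8 and 0.277, GALNT5 at 17.8 and 0.437 and ZNF544 at 35.6 and 3.6 were also higher in C2. BST2, the antiviral protein tetherin, was at 7.48 ± 1.02 CPM in C2 and 287 ± 20.5 in C1 (log2 -5.26, SE 0.18, adjusted p = 2.42e-13), and the cationic amino acid transporter SLC7A3 at 2.69 and 165, ALDH7A1 at 3.41 and 76.6, IAH1 at 0.330 and 29.3 and ATAD1 at 1.15 and 101 were also lower. In all 215 genes were called, 100 higher and 115 lower in C2, 182 of them at least 2-fold, and 16 of the 188 genes shared by both clones against A also differed between the clones. With no filter on low counts 345 were called, with DESeq2 253, and without both A replicate 2 libraries 280.

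Of the lists, TAL1, a haematopoietic transcription factor, was the only one of 6 tested haematopoietic genes called, at 3.48 ± 0.848 CPM in C2 and 48.6 ± 2.68 in C1 (log2 -3.78, adjusted p = 6.84e-11), and TNFAIP2 the only one of 11 NF-kB targets. Camera called the haematopoietic (adjusted p = 0.0316), NF-kB (0.0203) and ribosomal (0.00121, median -0.11, 0 of 76 called) lists lower and the G2/M list (0.00944, median 0.10, 36 of 46 positive, 0 called) higher in C2. None of these held: the adjusted p was 0.105, 0.0915, 0.0915 and 0.276 with an estimated correlation, in that order. The haematopoietic call was also lost without C2 DMSO replicate 1 (adjusted p = 0.137), C1 DMSO replicate 2 (0.0886) or C1 DMSO replicate 3 (0.0502) and with the replicate block (0.063). The NF-kB call was lost without C1 DMSO replicate 2 (0.0542) or C2 DMSO replicate 3 (0.127), and the G2/M call without C2 DMSO replicate 1 (0.0644) or C1 DMSO replicate 3 (0.0502) and by fry (0.0718).

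The median log2 fold change of the genes on a chromosome lay between -0.08 (chromosome 4) and 0.05 (chromosome 22) for C1 against A in DMSO, and between -0.10 (chromosome 19) and 0.03 (chromosome 2) for C2. In Nutlin-3 it lay between -0.07 (chromosome 19) and 0.02 (chromosome 8) for C1 and between -0.13 (chromosome 19) and 0.06 (chromosome 4) for C2. For C2 against C1 in DMSO it lay between -0.09 (chromosome 19) and 0.09 (chromosome 4). These medians are descriptions without a test.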

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

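The comparison with p53 targets, the comparisons with A libraries of different numbers, the omission of both A replicate 2 libraries and the look at the single A line were chosen only after the results were seen, and the other tests before.

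Several genes named for the C clones differed between C2 and C1 in DMSO by the edgeR test of that difference. Among genes called in both clones against A, the C2 minus C1 log2 difference was -1.48 for ANGPTL2 (adjusted p = 0.000942), -2.36 for THY1 (adjusted p = 2.45e-07), 1.06 for FAM19A5 (adjusted p = 0.00485), -3.62 for FASTKD2 (adjusted p = 0.0114), -1.61 for ACTL8 and -2.97 for AMBN. FAM19A5 lost this call without C1 DMSO replicate 2 (adjusted p = 0.0607), and FASTKD2 without C1 DMSO replicate 1 (0.0615), C2 DMSO replicate 2 (0.0657) or C2 DMSO replicate 3 (0.0874). Among genes called in C1 alone it was -3.56 for EPHX2, -1.37 for GRIA2, -1.20 for ARHGAP44, -1.18 for QPRT, 4.28 for IRX4, 3.01 for ZNF256, 3.96 for EMC10, 2.20 for SYK and 2.18 for ANXA1. Among genes called in C2 alone it was 2.18 for DLK1, 2.17 for AC091493.2, -6.37 for TNFAIP2, -7.09 for SERPINB9, -6.46 for IAH1 and -6.43 for ATAD1. Genes called in 1 clone alone were chosen on these same libraries, which favours a difference between the clones beforehand. The fitted difference was 7.97 for RAB39B, 6.54 for CHMP4C and -6.62 for RP3-522D1.1, but 1 clone had 1, 2 and 1 counts of them, with counting intervals of the ratio of 61.9 to 13800, 30.1 to 917 and 22.5 to 5060. Of list members, FTL differed by -0.42 (adjusted p = 0.041) and MAL2 by -3.34 (adjusted p = 0.00727). The ATF4 and ER stress list differed between the responses of the C clones and A by camera, with an adjusted p of 0.00207 for C1 and 0.0251 for C2, and 0.317 and 0.618 with an estimated correlation.

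Libraries were also regrouped at random. For each comparison of 3 against 3 the 10 splits are too few for a share under 0.05. The real split called 364 genes for C1 and 447 for C2 against A in DMSO, 360 and 556 in Nutlin-3, and 215 for C2 against C1, and the highest other split 0, 0, 0, 1 and 0, so that 1 split of 10 gave as many in each. For Nutlin-3 in C1 and C2 the real split called 3 and 1 genes and the highest other 0 and 0, again 1 of 10. For Nutlin-3 in A the real split called 0, which all 10 of the 10 splits reach by necessity, and the highest called 1768. That split put A DMSO replicates 1 and 2 with A Nutlin-3 replicate 2, which points to a structure of the samples around replicate 2. The numbers paired the samples in this comparison and in C1 against A in DMSO, and in both the highest of the other splits among the 4 that part all pairs called 0. For the difference of response, the real count was 0 for each clone, which all 50 of 50 regroupings reach by necessity, so they say nothing about chance. The highest called 320 for C1 and 1564 for C2, which again points to structure among the libraries.

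Nutlin-3 raised the ATF4 and ER stress list without a group rise of p53 targets. Chance is argued against for the list, since 1 of 100 regroupings, the real one, gave a camera p as small (negative log10 p 39.6, highest other 18.8). The count of 50 genes was reached by 2 of 100. The other, with 1755 genes, was a split that put both A replicate 2 libraries on one side. Structure among the libraries can therefore call more genes than Nutlin-3 did, and the count alone is weaker evidence than the list. A trend with GC content or transcript length is argued against, since the list's median was 0.36 (0.28 to 0.44) after such trends over 11827 genes were removed. A rise of p53 targets of the same size is argued against too, since the 67 targets outside the list had a median of -0.03 with an upper bootstrap bound of 0.0021. Activation of ATF4 by the drug or its handling, apart from p53, may be the source, but no sample without p53 or with another MDM2 inhibitor was given, so this stays an untested hypothesis. No p53 protein or activity was measured, so whether p53 can activate its targets in these cells is not known from these data. The flat targets therefore say nothing about MDM2 inhibition in other cells.

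In DMSO 188 genes differed from A with the same sign in both C clones. As many were called in 1 of 100 regroupings of the 9 DMSO libraries, the real one (188, highest other 91). Most such regroupings mix libraries of different lines, which widens the spread within groups, so they show only that the lines differ. The regrouping with 91 put all C2 libraries in the place of A, so 91 shared genes arose without A as the reference. Noise of the A libraries used in both comparisons is argued against by at least 111 genes shared between comparisons with no library in common and A libraries of different numbers, and the A replicate 2 libraries by 183 of the genes still called in both clones without them. A difference of the single A line unrelated to the allele cannot be told apart from an effect of the allele, because there was only 1 A line, and the C clones themselves differed in 215 genes. An effect of the C allele on these genes therefore stays open beside divergence of the lines.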

How the results depend on the processing

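Only the fit without both A replicate 2 libraries was chosen after the data were seen. The ATF4 and ER stress list in the mean response kept direction and call under every alternative run, when 1 library was left out at adjusted p = 1.91e-39 to 7.85e-32. Counts of called genes moved more, and the cause was not tested. With DESeq2 Nutlin-3 called 7 genes in A, 7 in C1, 22 in C2 and 147 in the mean. With no filter on low counts these were 38, 51, 86 and 159, the clones against A had 630 (C1) and 676 (C2) in DMSO and 567 (C1) in Nutlin-3, C2 against C1 345, both clones in DMSO 293, and the differences of response 31 (C1) and 26 (C2). With only the libraries of the groups compared, fewer samples set the spread: Nutlin-3 called 14 in C1 and 21 in C2, and the clones against A had 211 and 249 in DMSO and 215 and 315 in Nutlin-3. This was not run for the mean response, which compares all 18 libraries. Without both A replicate 2 libraries Nutlin-3 called 2 in A, 9 in C1, 22 in C2 and 98 in the mean, C1 against A had 1455 in DMSO and 728 in Nutlin-3, C2 against A 909 in DMSO, both clones 541, and the difference of response of C1 1. Leaving out 1 library gave 0 to 2, 0 to 3 and 1 to 2 for Nutlin-3 in A, C1 and C2, 23 to 95 for the mean, 225 to 495 and 301 to 498 for C1 and C2 against A in DMSO, 253 to 449 and 393 to 507 in Nutlin-3, 160 to 183 for C2 against C1, 128 to 228 for both clones, and 0 to 0 for each difference of response. The replicate block changed no call count by over 1.5 times in the 2 comparisons where the numbers paired the samples (0 for Nutlin-3 in A, 420 for C1 against A in DMSO). The block was shared by all lines, so it cannot remove deviations that the A libraries alone share. A pairing within A was not fitted, so the 0 for Nutlin-3 in A was not tested against it. In the other comparisons numbers are only shared, and the block moved Nutlin-3 in C2 from 1 to 4, while 14 of 18 libraries correlated best with one of their own number. RLE factors moved no count by over 1.5 times. CDKN1A, not called, turned sign at -0.0733 without C1 DMSO replicate 1 and -0.175 without A DMSO replicate 3 (C1 against A in DMSO, range -0.17 to 0.52), and at -0.0135 without C2 DMSO replicate 2 and -0.187 without A DMSO replicate 3 (C2, range -0.19 to 0.51). Of 20 other list calls an estimated correlation ended 12, fry 3, the block 1 (haematopoietic genes, C2 against C1, adjusted p = 0.063), the omission of both A replicate 2 libraries 2 and RLE 0, and 22 of 144 omissions of 1 library did. Of named genes DESeq2 ended 2 of 207 calls, RLE 1, no filter 5, the block 3 and the omission of both A replicate 2 libraries 4, the compared libraries alone 15 of 180, and omissions of 1 library 195 of 1542. Of simulated differences of response, 1.54% (C1) and 0% (C2) were called at 1.5-fold and 30.8% and 43.3% at 2-fold, so the 0 called do not exclude differences of this size.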

Other observations

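The neighbours below and the test on random orders of the tested genes were chosen after their values were seen, and apart from that and edgeR no test was run on them. Runs of adjacent genes were low against A in DMSO (log2 fold change below -2). In C1 the homeobox genes IRX4 and IRX2 with CTD-2194D22.3 between them (chromosome 5, 1877541 to 2752969) were at -4.34 to -2.57, and OLFM3 and COL11A1 (chromosome 1, 102268130 to 103574052) at -4.85 to -3.24. In C2 BST2 with the neighbours CTD-2521M24.5 and CTD-2521M24.9 (chromosome 19, 17502238 to 17529713) was at -4.89 to -3.36, and the troponin genes TNNT1 and TNNI3 (chromosome 19, 55644162 to 55669141) at -3.83 to -2.78. In both clones CTD-3064H18.1 was low beside ZNF793 (chromosome 19, 37988063 to 38039664). In all C1 had 90 such genes and 7 runs of at least 2, and C2 130 and 9. A run of 3 appeared in 0.36% of 10000 random orders for C1 and in 1.21% for C2.

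TAL1 was higher than in A in C1 (log2 2.12, adjusted p = 1.07e-07) and lower in C2 (log2 -1.66, adjusted p = 3.4e-05) in DMSO. The neuronal tubulin TUBB3 was lower in both (log2 -0.98 and -1.05) and MAP2 higher in C2 (log2 1.24, adjusted p = 0.00102). The pro-apoptotic HRK was lower in both clones in DMSO (log2 -0.99 and -0.71), and UBE2S was the only called gene of the G2/M list in each (log2 -2.81 and -2.85). The camera adjusted p of the haematopoietic list was 0.366 in C1 and 0.0615 in C2. Also lower were EPCAM in C1 (log2 -3.32, adjusted p = 0.006) and the interferon-stimulated BST2 in C2 (log2 -4.89), while SPARC was higher in C1 (log2 1.01, adjusted p = 0.00293). These members were chosen after their values were seen.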
